A study of Homo sapiens with 12 samples.

How the data were processed

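RNA sequencing libraries were made from whole cells and from exosomes of a 1:1 co-culture of MRC5 lung fibroblasts and 1833 breast cancer cells. Per the labels' protocols, samples were kept at 37 °C for 30 min in a calcium-containing buffer without nuclease, with MNase, or with MNase and 0.1% Triton X-100; exosomes came from conditioned medium by ultracentrifugation or by polyethylene glycol precipitation, and which was used for a library is not given in the sources used here. Per the labels' protocols RNA was extracted with TRIzol and libraries were built with a strand-keeping kit (NEBNext Ultra Directional), with the fragmentation step left out for exosome RNA only, so that exosome and cell libraries differ in preparation as well as in source. Detergent without nuclease was not analysed here, and the labels name no spike-in, so levels are relative within a library.

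The authors' table, as deposited, holds raw whole-number counts per Ensembl gene, per ribosomal or 7SL RNA sequence and per repeat element, not normalized. Per the submitters' processing notes, CASAVA, cutadapt 1.9, Bowtie2 2.2.4, STAR 2.4.0k, SAMtools and Subread 1.4.6 and the builds GRCh38 and GRCm38 (mm10) were used, with no order or role given; how reads with several positions were counted is not given in the sources used here. The table has 3125559 features: 66203 Ensembl genes, 12 named RNA sequences (7SL, the parts of the rRNA repeat, 5S and mitochondrial rRNAs) and 3059344 repeat elements in 846 families. Each count column was matched to its sample by the sample's title, with 0 columns left unmatched. Of the genes, 57055 are in GENCODE 29, which gave gene types and GRCh38 positions, and 26692 have no symbol in the table. The gene entry of RN7SL1 holds 0 counts, while 7SL reads stand under a separate sequence of 299 nt; the 5S entry covers a repeat unit of 2231 nt, more than the mature RNA. The gene entries of RMRP and RPPH1 also hold 0 counts, for a reason not given in the sources used here. Counts of near-identical copies (RN7SL, U1, histone and ribosomal protein genes, and nuclear copies of mitochondrial rRNA) are uncertain, and both mitochondrial rRNAs appear both as a sequence and as the genes MT-RNR1 and MT-RNR2.

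Groups were taken from the labels: 2 fractions with 3 treatments of 2 libraries each. Genes and named RNAs were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05), and files were read with the data.table package, version 1.17.8. The 6 exosome libraries were fitted together (13169 features passed the filter, biological coefficient of variation 6.47%, 3 residual degrees of freedom), as were the 6 cell libraries (3823, 8.41%, 3). Exosomes against cells and the 2 interactions used all 12 (16928, 9.06%, 6), for 9 comparisons in all. Repeat families, summed over elements, were tested apart with the gene-level factors. 20 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, where a list had at least 3 tested members. Lists, comparisons, the tests named here and the naming rule were fixed before the data were examined; of the 8 tests of causes, 6 were written only after the result was seen.

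Named genes followed a fixed rule: all tested members of the SRP RNA and RNA polymerase III small RNA lists; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 10 CPM and, outside the interactions, no overlap between groups, leaving out pseudogenes and clone-based names; and from every other list up to 2 members with the smallest p. A gene named for one comparison may be given in the others. UBE2Q2P2 and CTHRC1 fall outside the rule. The lists were SRP RNAs, RNA polymerase III small RNAs, SRP proteins, interferon-stimulated genes, mitochondrial mRNAs and rRNAs, cytosolic and mitochondrial ribosomal protein genes, histone mRNAs, spliceosomal snRNAs, C/D and H/ACA snoRNAs, nuclear long noncoding RNAs, glycolysis, ER chaperone and proliferation genes, markers of MRC5-like fibroblasts, of carcinoma cells and of blood and serum, and exosome-associated protein genes. A gene with no count in 1 group is given as a bound against a floor of 3 counts over the group; intervals of shares are Wilson 95% intervals, and a ratio resting on 1 to 3 counts is given with its exact (Clopper-Pearson) 95% counting interval, scaled by the TMM factors.

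Alternatives tried were RLE factors, library size alone, no low-count filter, a minimum of 50 counts in 2 libraries, DESeq2 1.42.0, the replicate number as a block, no rRNA or mitochondrial genes, all 12 libraries or the 4 untreated ones in the fit, each library left out, repeat families with their own factors, fry in place of camera, and, added after the data were seen, all assigned counts as library size. Replicate pairs were compared with a chi-square test over genes, named RNAs and repeat families of 100 or more counts: the statistic per degree of freedom was 21.1, 6.62 and 64.9 in untreated, MNase and Triton plus MNase cells and 8.33, 2.31 and 1.69 in the exosomes of these treatments, more than sampling noise in each pair. Over gene-level features alone, with 10 or more counts, it was 1.16 and 1.06 in untreated and MNase exosomes and 0.947 (chi-square p = 1, 8177 features) in Triton plus MNase exosomes, where the pair differed by no more than sampling noise at that level. Since the more deeply counted features, repeat families included, set that pair apart (chi-square p = 1.87e-24), it was kept as 2 replicates.

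Gene and named RNA counts per library, on which the tests rest, ranged from 4638428 to 7534242 in cells, from 1195663 to 1900161 in untreated and MNase exosomes, and were 170812 and 232588 in Triton plus MNase exosomes. The test was run on simulated counts with 200 changed genes, drawn among those with a mean of at least 12 counts per library. Recovery of genes below that count was not tested. How closely the simulated libraries matched the real ones in depth and composition was not tested either. For Triton plus MNase against untreated exosomes (13169 genes) it found 52.2%, 94% and 98.5% of genes changed 2-, 4- and 8-fold, with 4.12% false calls among 170. For the same contrast in cells (3823 genes) it found 46.3%, 91% and 98.5%, with 4.27% false among 164, and for untreated exosomes against cells (16928 genes) 47.8%, 92.5% and 98.5%, with 1.24% false among 161. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.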

Results

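RNA was sequenced from co-cultures of MRC5, a human lung fibroblast line, and 1833, a bone-tropic subline of the MDA-MB-231 breast cancer line, mixed 1:1. Whole cells and the exosomes they released were each incubated for 30 min with buffer (untreated), with micrococcal nuclease (MNase), or with 0.1% Triton X-100, a membrane-dissolving detergent, and MNase together. The 2 fractions and 3 treatments made 6 groups of 2 libraries, 12 libraries in all. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. All assigned counts, repeats included, ranged from 4689147 to 7572118 in cell libraries and from 1113992 to 2667039 in exosome libraries. The comparisons ask which RNAs the nuclease reaches in each fraction, alone and after membranes are dissolved, with 7SL RNA, the RNA of the signal recognition particle (SRP), at the centre.

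7SL RNA made up most of what was counted in untreated exosomes and almost none of it after detergent and nuclease. Its share of all assigned counts was 61.1% ± 1.9 (SD, n = 2) in untreated exosomes, 49% ± 0.168 after MNase and 0.248% ± 0.00755 after Triton plus MNase. In cells the shares were 0.833% ± 0.0443, 0.766% ± 0.0163 and 0.695% ± 0.0203 in the same order. Cytoplasmic ribosomal RNA (rRNA) filled the cell libraries, with 90.0% ± 0.777 in untreated cells against 3.51% ± 0.00240 in untreated exosomes. Transposons, satellites and other repeats held 29.8% ± 1.66 of untreated exosome counts, 84.7% ± 0.215 after Triton plus MNase, and 0.0402% ± 0.00166 in untreated cells. Protein-coding genes held 2.90% ± 0.165 of untreated exosome counts and 6.76% ± 0.111 after Triton plus MNase. Replicate 2 of the Triton plus MNase exosomes had 3759 counts of 7SL RNA among 1546843, a share of 0.243% with a Wilson 95% interval of 0.235% to 0.251%. Intervals and floors cover counting error only. With 2 libraries against 2, shares were not tested.

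**Figure D1:**
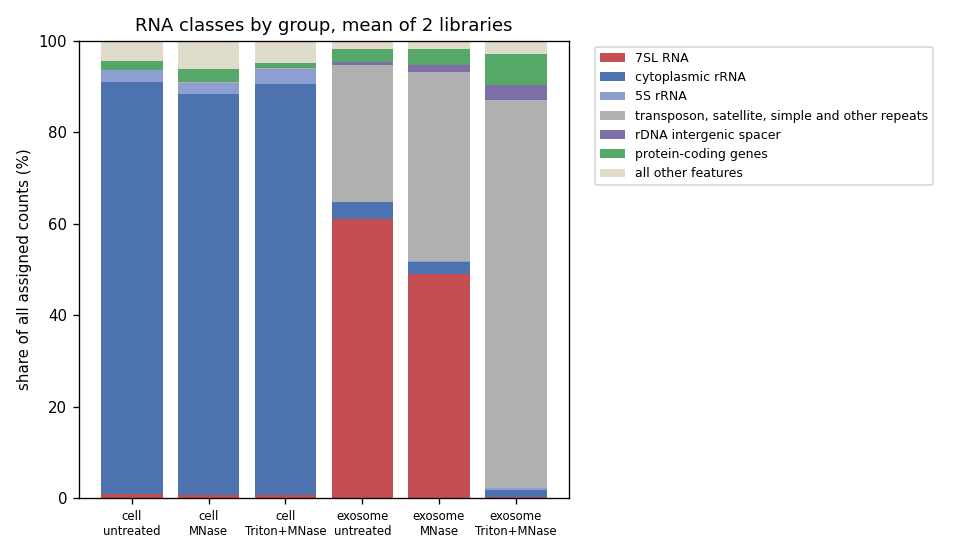
Mean share of all assigned counts (%, vertical axis) of RNA classes in each of the 6 groups, with 2 libraries per group. The 7SL segment fills 61.1% of untreated exosomes and 0.248% after Triton plus MNase, while the repeats go from 29.8% to 84.7%.

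**Figure D2:**
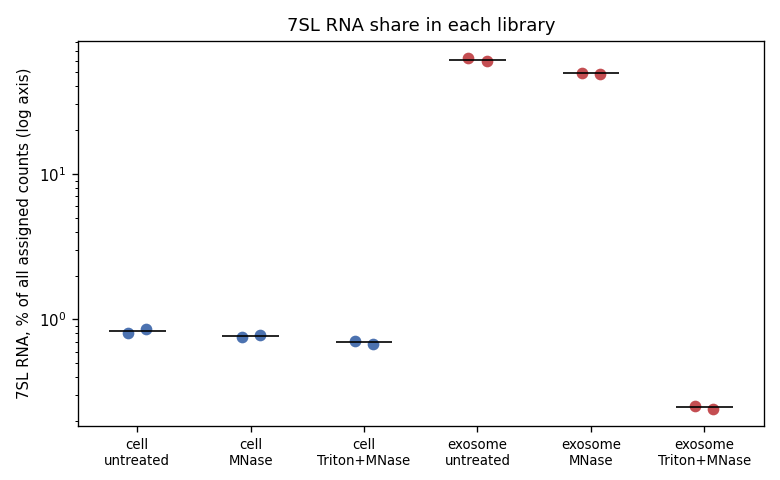
Share of 7SL RNA in each library (% of all assigned counts, log axis); points are libraries and lines are group means. The untreated and MNase exosome libraries sit between 48.9% and 62.5%, and the Triton plus MNase exosome libraries at 0.254% and 0.243%, below every cell library.

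7SL RNA was far lower in exosomes after Triton plus MNase under every scaling tried. The Y RNAs were lower too, by an amount that shrank to between -1.63 and -0.52 (log2) with library size alone, while VTRNA1-1 and VTRNA1-2, vault RNAs of a large cytoplasmic particle, were lower with TMM factors and higher with library size alone. Against untreated exosomes, 7SL RNA fell by 9.25 on the log2 scale (SE 0.10, adjusted p = 4.43e-71), or 608-fold. Its near-identical gene copies RN7SL3 and RN7SL2, which may share its reads, were at -7.70 and -5.05; RN7SL3 was at -8.77 without treated replicate 1 and -6.90 without replicate 2. RNY1 (ENSG00000201098, chromosome 7 of GRCh38, 148987136 to 148987248) and RNY4 (148963315 to 148963410 on the same chromosome), Y RNAs bound by the Ro60 protein, changed by -5.39 (SE 0.21) and -4.29 (SE 0.22), and were at -1.63 and -0.52 with library size alone. RNY3 changed by -4.55 (-5.98 without treated replicate 2), and with library size alone it was at -0.83 and did not pass the test.

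VTRNA1-1 (ENSG00000199990, chromosome 5, 140711275 to 140711373) and VTRNA1-2 changed by -0.91 (adjusted p = 0.000156) and -1.10, but turned to 2.87 and 2.67 when libraries were scaled by size alone, to 0.40 and 0.21 with all assigned counts, and to 1.80 and 1.63 with a minimum of 50 counts. VTRNA1-3, at -0.73 (adjusted p = 0.626) and 3.03 with library size alone, did not pass with TMM factors. RN7SK, the RNA of the 7SK transcription-control particle, was at -2.38 and turned to 1.36 with library size alone; it was at -3.74 without treated replicate 1 and at -1.48 without replicate 2 (adjusted p = 0.1). MT-CYB, mitochondrial cytochrome b, was at -1.47 and turned to 2.28 with library size alone; its adjusted p was 0.119 without untreated replicate 2 and 0.0783 without treated replicate 1. The U1 and U4 spliceosomal RNAs RNU1-1 and RNU4-2 changed by -1.79 and -1.89, and GAPDH, a glycolytic enzyme, by -3.33; these turned to 1.98, 1.87 and 0.40 with library size alone, and RNU1-1 and RNU4-2 to 0.92 and 0.77 with the minimum of 50 counts. 5.8S rRNA fell by 4.33. The 2 higher features were the 5S rRNA sequence, at 1.12, and the intergenic spacer of ribosomal DNA (IGS), at 0.94. The 5S entry covers a whole repeat unit, so its rises here and below may come from mature 5S rRNA, from spacer sequence or from both. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 of 13169 features were higher (5 without treated replicate 2) and 41 lower. With library size alone, 13137 were higher and 13 lower, with all assigned counts as library size 2959 and 32, and with the minimum of 50 counts, over 40 features, 19 and 15.

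The 3 tested members of the SRP RNA list are 7SL RNA and copies that may share its reads (estimated correlation 0.902). Its list results, here and below, add little beyond those of 7SL RNA. All 3 members of the SRP RNA list fell, also adjusted over the list alone, and 6 of 8 RNA polymerase III small RNAs fell, 7 adjusted over the list alone. With an estimated correlation the adjusted p was 0.00358 and 0.00358; with library size alone 5 of the latter list were higher and 2 lower. Spliceosomal snRNAs had 4 of 8 members lower, 5 adjusted over the list alone (adjusted p = 0.0321 with an estimated correlation), and with library size alone 8 were higher. Mitochondrial mRNAs had 1 of 12 lower, 7 adjusted over the list alone, and the list's call was lost with an estimated correlation (adjusted p = 0.0688); with library size alone 12 were higher. For the 55 cytosolic ribosomal protein genes, of which none passed in edgeR or adjusted over the list alone, camera's call of a lower list was likewise lost (adjusted p = 0.17 with an estimated correlation). Among repeats, 44 of 51 Alu families were higher with the gene-level factors and 48 with factors from the repeats themselves. Of 131 L1 families, 11 were higher and 70 lower with the gene-level factors, but 17 higher and 5 lower with their own, and of 500 LTR families 7 and 154, then 23 and 39.

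The direction of most exosome changes differed between scalings, and the labels name no spike-in. Library size is the sum of the tested features, and 7SL RNA held 1665921 of its 1867515 counts in untreated exosome replicate 1. Under that scaling the fall of 7SL RNA itself pushes the other exosome features up. Exosome values that turn with library size alone, here and elsewhere, may therefore follow in part from 7SL RNA. The median feature shifted by 3.70 (log2) with library size alone and by 1.37 with all assigned counts, so changes are given relative to the TMM factors. Those factors rest on 13169 exosome features, of which 40 reached 50 counts in 2 libraries. The rest had lower counts, which may come in part from genomic DNA, a source left open below. Exosome folds and calls are therefore relative to a base of uncertain origin. 7SL RNA stayed lower under every scaling tried, at -5.48 with library size alone.

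**Figure D3:**
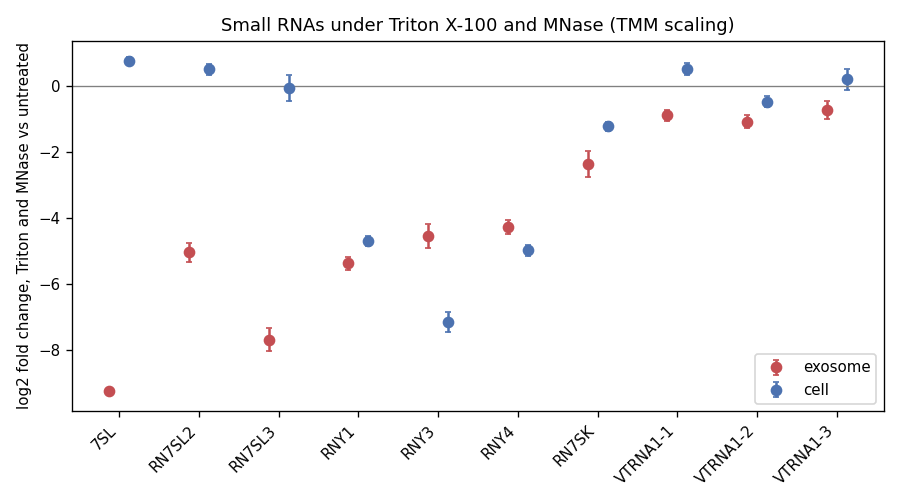
Log2 fold change, Triton plus MNase against untreated (vertical axis), of 10 small RNAs in exosomes (red) and cells (blue) under TMM scaling; bars are standard errors. 7SL RNA lies at -9.25 in exosomes and 0.74 in cells, while RNY1 lies at -5.39 and -4.70; with library size alone the cell values of 7SL RNA, RN7SL2, VTRNA1-1 and VTRNA1-3 turn to -0.27, -0.51, -0.50 and -0.81, and the exosome values of VTRNA1-1, VTRNA1-2, VTRNA1-3 and RN7SK turn to 2.87, 2.67, 3.03 and 1.36.

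With MNase alone the change of 7SL RNA in exosomes was smaller. 7SL RNA fell by 0.62 (SE 0.073, adjusted p = 3.24e-08), or 1.54-fold, and RNY4 fell by 1.38. VTRNA1-1 was at -0.88, VTRNA1-2 at -1.14, 5.8S rRNA at -1.37, RNU1-1 at -1.27 and mitochondrial 16S rRNA at -1.25, all past the test. RNVU1-7, a variant U1 gene, fell by 0.97 (adjusted p = 0.0272). RNY1, at -0.47, and GAPDH, at -1.0, did not pass the test (adjusted p = 0.498 and 0.0737), and RNY1 turned to 0.091 with library size alone and 0.037 with a minimum of 50 counts. The 5S rRNA sequence was higher by 1.01, IGS by 0.71, and the third higher feature was the pseudogene UBE2Q2P2, named after its values were seen, with 13 counts against 0, at least 4.40-fold higher (floor of 3 counts over the group). UBE2Q2P2 lost its call without untreated replicate 1 or 2 (adjusted p = 0.359 and 0.461), without the low-count filter (0.148), without rRNA and mitochondrial genes (0.0648), with the replicate block (0.213), with all 12 libraries in the fit (0.0842) and in DESeq2 (1). In total 3 of 13169 features were higher and 15 lower; with library size alone 30 were higher and 4 lower. With a minimum of 50 counts, which left 40 features, 1 was higher and 0 lower by edgeR's quasi-likelihood test, with 6 at an unadjusted p under 0.05 in either direction; DESeq2, on all features, called 9 lower.

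Without replicate 1 of the MNase exosomes the lower count was 5, and calls were lost at -0.62 for 7SL RNA (adjusted p = 0.0529), -0.58 for VTRNA1-1 (0.611), -0.80 for VTRNA1-2 (0.467) and -0.95 for RNVU1-7 (0.468). With each of the 4 libraries left out in turn, 7SL RNA was between -0.71 and -0.51. RNVU1-7 also lost its call without MNase replicate 2 (adjusted p = 0.325) or untreated replicate 1 (adjusted p = 0.186). Library size alone left 7SL RNA at -0.050, VTRNA1-1 at -0.30, VTRNA1-2 at -0.56, 16S rRNA at -0.68 and RNVU1-7 at -0.40, none past the test. 7SL RNA made up 1002779 of the 1165386 counts of that size in MNase replicate 1, so this scaling could not test its change. RNA polymerase III small RNAs had 3 of 8 members lower, 7 adjusted over the list alone (adjusted p = 0.0428 with an estimated correlation). The SRP RNA list had 1 of 3 lower, 3 adjusted over the list alone, and its camera call was lost with an estimated correlation (adjusted p = 0.206). So were the calls of mitochondrial mRNAs (8 of 12 lower adjusted over the list alone, none over all features, adjusted p = 0.128) and spliceosomal snRNAs (2 of 8 lower, 5 adjusted over the list alone, adjusted p = 0.103). Alu families were higher in 38 of 51 cases, and in 43 with factors from the repeats themselves.

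7SL RNA and RNY1 were also far lower in exosomes with Triton added to MNase than with MNase alone. Relative to the TMM factors, 7SL RNA fell 396-fold (log2 -8.63, adjusted p = 1.06e-69), and RNY1 fell by 4.92. Among all assigned counts the share of 7SL RNA was 49% with MNase and 0.248% with Triton added, so the fold depends on the scaling. RN7SL2 was at -4.59 and RN7SL3 at -7.12 (-8.19 without treated replicate 1 and -6.33 without replicate 2). RNY3, at -3.71 (-5.16 without treated replicate 2), and 18S rRNA, at -3.34, lost their calls with library size alone, at -0.56 and -0.14. RNY4, at -2.91, and GAPDH, at -2.32, turned to 0.28 and 0.84 under that scaling. VTRNA1-1 and VTRNA1-2 differed by -0.033 and 0.041 (adjusted p = 0.99 for each), and with library size alone VTRNA1-1 turned to 3.17 and VTRNA1-2 was at 3.24. In total 27 of 13169 features were lower and 0 higher by edgeR's quasi-likelihood test, where 653 had an unadjusted p under 0.05 in either direction; DESeq2 called 1 higher, and edgeR 1 without treated replicate 1. With library size alone 13033 were higher and 10 lower, and with the minimum of 50 counts 23 and 12. The SRP RNA list fell in all 3 members, also adjusted over the list alone, and RNA polymerase III small RNAs in 3 of 8, 4 adjusted over the list alone (adjusted p = 0.00319 and 0.0119 with an estimated correlation). Camera's calls of lower spliceosomal snRNAs (4 of 8 adjusted over the list alone) and ribosomal protein genes were lost with an estimated correlation (adjusted p = 0.272 and 0.272).

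Untreated exosome libraries were rich in 7SL RNA and the vault RNA VTRNA1-1 and poor in ribosomal protein, histone, snoRNA and mitochondrial transcripts, compared with untreated cell libraries. Fragmentation was left out for exosome RNA only, so source and preparation cannot be told apart in this contrast. Sizes also depend on the denominator: over counts without ribosomal RNA, 7SL RNA held 15.7% in untreated cells and 63.9% in untreated exosomes. Relative to untreated cells, 7SL RNA was 42.9-fold higher (log2 5.42, SE 0.17), RN7SL3 was higher by 4.88, RN7SL2 by 2.10, VTRNA1-1 by 3.32, VTRNA1-2 by 1.52 and VTRNA1-3 by 1.35. The median feature was at 1.54, so VTRNA1-2 and VTRNA1-3 lay close to a typical feature. RNY3 and RNY4 were at -2.14 and -1.84, and RNY1, at -0.79, turned to 0.51 with library size alone; with the minimum of 50 counts RNY3, RNY4 and RNY1 turned to 1.19, 1.49 and 2.54. RN7SK was at -7.19, the U5 RNA RNU5A-1 at -8.20, GAS5, a long noncoding RNA that hosts snoRNAs, at -7.01, and RPL13A, a ribosomal protein gene, at -6.12. FN1, which encodes fibronectin, was at -5.30, COL1A1, a type I collagen chain, at -5.47, and MT-CO1, a cytochrome oxidase subunit, at -4.50. The mitochondrial tRNAs MT-TM, MT-TH and MT-TS2 had no count in untreated exosomes and were at least 708-fold, 249-fold and 195-fold lower (floor of 3 counts over the group), and the snoRNA SNORD13 at least 126-fold lower.

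Higher features included IGS, at 7.68, HELLPAR, a long noncoding RNA gene (ENSG00000281344, chromosome 12, 102197585 to 102402596), at 7.30 on 311 counts against 2 (ratio of scaled counts 179, exact 95% interval 49 to 1482), and TTN, which encodes the giant muscle protein titin, at 7.18 on 159 counts against 1 (ratio 183, exact 95% interval 32.3 to 7261). TTN was at 9.45 without untreated cell replicate 1 and 6.17 without replicate 2. By edgeR's quasi-likelihood test 7178 of 16928 features were higher and 2174 lower, and the median feature was at 1.54. With library size alone 10727 were higher and 1008 lower, with a median of 2.76, but with a minimum of 50 counts, which left 603 features, the balance turned to 143 higher and 180 lower, with a median of -0.21. The higher count was 3168 without untreated cell replicate 2, 4297 without untreated cell replicate 1 and 4779 without untreated exosome replicate 2. Of 6282 protein-coding genes with no count in any cell library, 82.7% had a count in an untreated exosome library, and over these genes the exosome count followed exonic length with a Spearman rho of 0.691; genes are not independent replicates. With gene-level factors 705 of 758 repeat families were higher and 47 lower, against 76 and 61 with factors from the repeats themselves.

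Each of the 20 lists was compared between untreated exosomes and cells. Lower were 13 of 13 mitochondrial mRNAs, 2 of 2 mitochondrial rRNAs, 16 of 16 spliceosomal snRNAs, 76 of 79 cytosolic ribosomal protein genes, 39 of 40 histone mRNAs, 21 of 22 C/D snoRNAs and 40 of 41 H/ACA snoRNAs, with 1 H/ACA snoRNA higher, each with the same count adjusted over the list alone. So were 15 of 15 endoplasmic reticulum (ER) chaperone genes, 17 of 18 fibroblast markers, 11 of 14 exosome-associated protein genes, with 1 higher, and 9 of 17 proliferation genes, again with the same counts adjusted over the list alone. Glycolysis genes had 14 of 18 lower, and 14 lower and 1 higher adjusted over the list alone. SRP protein genes had 4 of 8 lower, 5 adjusted over the list alone, and nuclear long noncoding RNAs 5 of 8 lower and 1 higher, 6 and 1 adjusted over the list alone. Mitochondrial ribosomal protein genes had 6 of 29 lower and 1 higher, 4 and 0 adjusted over the list alone, and with library size alone 6 were higher and 0 lower. Over the exosome libraries 2 histone mRNAs, 2 C/D snoRNAs and 0 H/ACA snoRNAs passed the count filter. Over the cell libraries 46, 29 and 47 passed. Most members of these lists were therefore tested because of their cell counts, which in part set the direction of their calls.

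Among the carcinoma markers 5 of 17 were higher and 3 lower, 4 and 3 adjusted over the list alone, with no call of the list (adjusted p = 0.257 with an estimated correlation). Interferon-stimulated genes had 11 of 24 higher and 2 lower, 12 and 2 adjusted over the list alone, and no call (adjusted p = 0.33 with an estimated correlation). Over all features 7178 of 16928 were higher. Only 4 of the carcinoma markers and 3 of the interferon-stimulated genes passed the count filter over the cell libraries, so many members were tested because of their exosome counts. 7 of 7 blood and serum genes, markers of cells outside the co-culture, were higher, also adjusted over the list alone (adjusted p = 0.0421 with an estimated correlation), on low counts. Of the list's 19 entries in the table, 7 passed the count filter over all 12 libraries and 0 over the cell libraries, so these members were tested because of their exosome counts. APOB had 23 counts against 0 and TF 14 against 0, at least 8.81-fold and 5.36-fold higher. The 3 SRP RNAs were higher, also adjusted over the list alone, and RNA polymerase III small RNAs had 3 of 8 higher and 4 lower, the same adjusted over the list alone; with an estimated correlation their calls were lost (adjusted p = 0.055 and 0.152), and with library size alone 5 of the latter list were higher and 3 lower. The calls of the other lists held with an estimated correlation, except mitochondrial rRNAs, too few for a test.

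In cells, MNase alone raised precursor rRNA spacers, mitochondrial mRNAs and nuclear long noncoding RNAs and lowered cytosolic ribosomal protein and histone mRNAs, relative to the TMM factors. The 5' and 3' external spacers and the second internal spacer (IS2) of the rRNA precursor rose by 2.95, 2.70 and 2.44, IGS by 3.45, and MIR3648-1, a microRNA gene within the rRNA precursor, by 3.35. NEAT1, the scaffold RNA of nuclear paraspeckles (ENSG00000245532, chromosome 11, 65422774 to 65445540), rose by 2.23 (SE 0.15, adjusted p = 3.71e-08) and MEG3 by 1.51. MT-ND5 and MT-ND4, subunits of respiratory complex I, rose by 1.58 and 1.45, and the H/ACA snoRNA SNORA74A by 2.93. RNY1, RNY3 and RNY4 were at -1.17, -0.80 and -0.82, RN7SK at -1.05 and VTRNA1-2 at -1.25, all past the test. CD63, an exosome-associated tetraspanin, fell by 1.41, and SNORD13, RNU6ATAC and 5.8S rRNA changed by -1.40, -1.55 and -1.21. Of 246 repeat families, 183 were higher and 14 lower with the gene-level factors (median 2.05), but 17 and 45 with factors from the repeats themselves (median 0.17).

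7SL RNA fell by 0.50 in these cells (SE 0.11, adjusted p = 0.00752), was at -0.12 and did not pass with library size alone, and lost its call without MNase replicate 1 (adjusted p = 0.103) or 2 (adjusted p = 0.0731), although its log2 value lay between -0.54 and -0.49 with any of the 4 libraries left out. VTRNA1-1 was at -0.58 (adjusted p = 0.0482), at -0.24 without untreated replicate 2 (adjusted p = 0.593), and lost its call without MNase replicate 1 or 2 (adjusted p = 0.0896 and 0.18) or with library size alone, at -0.20. BCYRN1, a brain cytoplasmic RNA, was at -0.95 (adjusted p = 0.0396) and lost its call with any of the 4 libraries left out, with adjusted p up to 0.161, or with library size alone, at -0.58. 13 of 13 mitochondrial mRNAs rose, also adjusted over the list alone (adjusted p = 0.0173 with an estimated correlation), as did 4 of 7 nuclear long noncoding RNAs, 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0436). Cytosolic ribosomal protein genes fell in 48 of 76 cases, 63 adjusted over the list alone, including RPL35 (-1.33) and RPL41 (-1.21), and histone mRNAs in 25 of 46, 36 adjusted over the list alone, including HIST1H1C (-1.31). Reads of ribosomal protein and histone genes may be shared with their near-identical copies. With library size alone 15 and 13 members of these lists were lower, and with an estimated correlation the adjusted p was 0.0173 and 0.0173. Spliceosomal snRNAs had 8 of 17 lower, also adjusted over the list alone, and C/D snoRNAs 7 of 29, 9 lower and 1 higher adjusted over the list alone; with an estimated correlation their adjusted p was 0.142 and 0.282, and with library size alone 3 and 2 members were higher and the medians turned from -0.36 and -0.36 to 0.013 and 0.016. In total 182 of 3823 features were higher and 214 lower, and with library size alone 615 and 69. The higher count was 108 without MNase replicate 2 and 112 without untreated replicate 2, and the lower count 128 without MNase replicate 2.

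The Y RNAs were far lower in cells as well after Triton plus MNase, while 7SL RNA was higher or lower depending on the scaling. Against untreated cells, RNY3 fell by 7.16 on 3 counts against 700 (ratio 149.9, exact 95% interval 51.1 to 728), RNY4 was at -4.99, RNY1 at -4.70 and RN7SK at -1.23, and BCYRN1 had 0 counts against 53, at least 11.3-fold lower. 7SL RNA was at 0.74 (SE 0.11, adjusted p = 6.13e-05), which turned to -0.27 with library size alone and -0.26 with all assigned counts as library size. RN7SL2 and VTRNA1-1, at 0.49 and 0.50, turned to -0.51 and -0.50 with the former scaling and -0.50 and -0.49 with the latter. RN7SL2 lost its call with any of the 4 libraries left out (adjusted p up to 0.168). VTRNA1-1 lost its call without untreated replicate 1 (adjusted p = 0.422) or treated replicate 2 (adjusted p = 0.18) and was at 0.83 without untreated replicate 2. VTRNA1-2, at -0.49, lost its call without treated replicate 1 or 2 or untreated replicate 2 (adjusted p = 0.119, 0.0811 and 0.222). IGS rose by 5.27, SNORA74A by 5.08, the 5' external spacer by 4.32, NEAT1 by 3.0, MEG3 by 2.60 and RNU1-1 by 1.54. SNORA13 rose by 4.88 (5.57 without untreated replicate 1 and 4.25 without replicate 2). MTRNR2L8, a nuclear copy of mitochondrial 16S rRNA whose reads cannot be told from the original with certainty, rose by 4.92. COL1A1 and COL6A1, collagen genes of fibroblasts, rose by 1.39 and 1.42, while MMP1, a secreted collagenase, fell by 2.13. CANX, an ER chaperone, and ANXA2, a membrane-binding protein gene, were at -1.99 and -2.77.

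The mitochondrial tRNAs MT-TH, MT-TM and MT-TS2 were at -4.33, -4.21 and -3.86 under this treatment. Mitochondrial mRNAs fell in 9 of 13 cases and rose in 2, the same adjusted over the list alone; MT-ATP6 was at -2.32 and MT-ND5 at 1.49. Ribosomal protein genes fell in 72 of 76 cases and histone mRNAs in 43 of 46, the same adjusted over the list alone, with RPL37A at -2.93, RPL41 at -3.65 (-4.26 without treated replicate 2) and HIST1H4K at -3.01. H/ACA snoRNAs rose in 43 of 47 cases, 44 adjusted over the list alone, and nuclear long noncoding RNAs in 5 of 7, 6 adjusted over the list alone; with library size alone 35 and 3 were higher and 3 and 2 lower. Spliceosomal snRNAs had 12 of 17 higher and 3 lower, also adjusted over the list alone, but 5 higher and 5 lower with library size alone. With an estimated correlation the adjusted p was 0.202 for mitochondrial mRNAs, 0.0577 for ribosomal protein genes, 0.0531 for histones, 0.0767 for H/ACA snoRNAs, 0.0577 for nuclear long noncoding RNAs and 0.217 for snRNAs, and none of these lists kept its call. Fibroblast markers had 6 of 17 higher and 5 lower, also adjusted over the list alone, and 2 higher and 12 lower with library size alone. In total 780 of 3823 features were higher and 761 lower. With library size alone 235 were higher and 1959 lower, and the median feature was at -1.03. Of the 3823 features behind the TMM factors of cells, 3535 were protein-coding genes. That class held 2.07% of all assigned counts in untreated cells, 2.71% after MNase and 1.05% after Triton plus MNase. Rises in Triton plus MNase cells, here and below, are therefore relative to genes whose share itself fell.

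**Figure D4:**
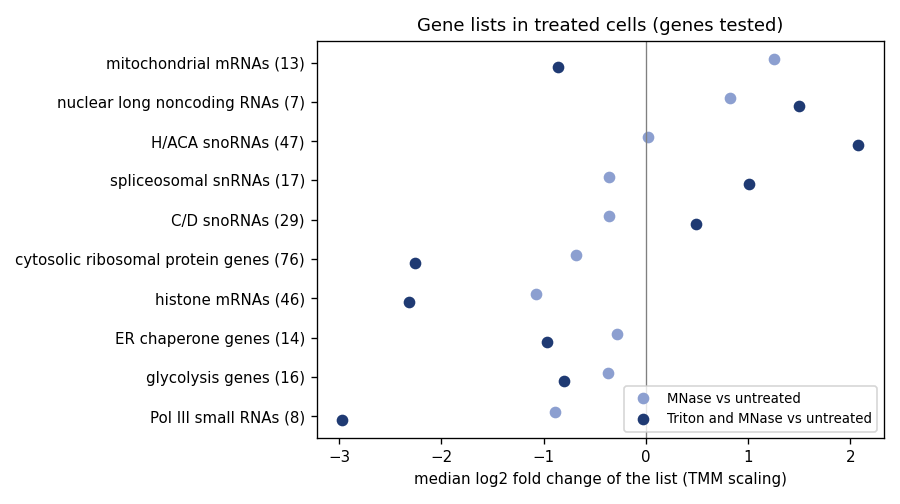
Median log2 fold change (horizontal axis, TMM scaling) of 10 gene lists in cells after MNase (light) and after Triton plus MNase (dark), each against untreated, with the number of genes tested in brackets. Mitochondrial mRNAs lie at 1.26 after MNase and -0.86 after Triton plus MNase; with library size alone these medians are 1.64 and -1.86, the dark point of C/D snoRNAs turns from 0.49 to -0.50, and the light points of spliceosomal snRNAs, C/D snoRNAs, glycolysis and ER chaperone genes turn to 0.013, 0.016, 0.011 and 0.10.

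In cells, mitochondrial mRNAs and Y RNAs were lower with Triton plus MNase than with MNase alone, and H/ACA snoRNAs were higher. MT-TM, MT-TH and MT-TS2 were at -4.31, -4.21 and -3.69, MT-ATP6 at -3.58, MT-CO1 at -1.86 and RPL5 at -2.85. LDHA, lactate dehydrogenase, was at -2.46 and at -3.19 without treated replicate 2. RNY3 fell by 6.36 (ratio 86.3, exact 95% interval 29.4 to 420), RNY4 and RNY1 were at -4.17 and -3.53, and BCYRN1 was at least 5.83-fold lower. SNORA74A rose by 2.15, SNORD17 by 2.14, SNORA80E by 2.11, SNORA65 by 2.02 and SNORA73B by 1.73. 7SL RNA, at 1.24, RN7SL2, at 0.92, VTRNA1-1, at 1.08, VTRNA1-2, at 0.77, and COL1A1, at 1.05, turned to -0.15, -0.46, -0.30, -0.61 and -0.34 with library size alone, and to -0.14, -0.45, -0.29, -0.60 and -0.33 with all assigned counts. VTRNA1-2 lost its call without treated replicate 2 (adjusted p = 0.0874). Mitochondrial mRNAs fell in 11 of 13 cases, also adjusted over the list alone (adjusted p = 0.0381 with an estimated correlation), and H/ACA snoRNAs rose in 46 of 47, also adjusted over the list alone (adjusted p = 0.0495); with library size alone 22 of these were higher and 1 lower. In total 577 of 3823 features were higher and 522 lower, against 54 and 2791 with library size alone. The lower count was 338 without treated replicate 2.

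Whether exosomes and cells responded differently was tested as an interaction over the 12 libraries. Fragmentation was left out for exosome RNA only, so fraction and preparation cannot be told apart in the interactions either, here and below. For MNase alone, 7SL RNA was at -0.25 (adjusted p = 1, exosome minus cell, and 0.070 with library size alone and 0.030 with RLE factors), while 36 of 16928 features responded lower in exosomes than in cells and 2 higher. The lower count was 22, 23 and 23 without untreated exosome replicate 1, untreated exosome replicate 2 and MNase exosome replicate 2; the higher count was 1 without untreated cell replicate 1, MNase cell replicate 1, MNase exosome replicate 1 or 2, or untreated exosome replicate 2. For Triton plus MNase, the response of 7SL RNA was at -9.74 (SE 0.24) and that of RN7SL3 at -7.39 (-8.45 without treated exosome replicate 1 and -6.62 without replicate 2). RNY1, RNY3 and RNY4, at -0.45, 2.82 and 0.95, did not pass the test, and RNY1 turned to 4.0 with library size alone and 1.60 with all assigned counts. In total 66 features were higher and 105 lower, against 8808 and 5 with library size alone. The higher count was 32, 39, 33 and 32 without untreated exosome replicate 1, untreated exosome replicate 2, treated exosome replicate 1 and treated exosome replicate 2. The lower count was 67, 58 and 67 without untreated exosome replicate 1, untreated exosome replicate 2 and treated cell replicate 2.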

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

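The tests of causes for 7SL RNA and for the precursor rRNA spacers were chosen only after the result was seen; the interaction tests were planned. Genes are first given with their treatment effect, exosome minus cell, where it passed edgeR's quasi-likelihood test of that difference over the 12 libraries; the tests of causes at the end use other values.

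For MNase alone 2 features responded higher in exosomes and 36 lower. The 2 higher were the 5S rRNA sequence, whose entry includes spacer, at 1.45, and CTHRC1, a fibroblast-secreted protein gene named after its values were seen, with 10 counts in MNase and 1 in untreated exosomes (ratio of scaled counts 10.2, exact 95% interval 1.45 to 443; adjusted p = 0.0485). CTHRC1 was at 3.69 without untreated exosome replicate 1 and 6.95 without untreated exosome replicate 2, and lost its call without either of these (adjusted p = 0.486 and 0.127), MNase exosome replicate 1 or 2 (0.113 and 0.464), untreated cell replicate 1 (0.189) or MNase cell replicate 1 (0.182), without the low-count filter (0.208) and with the replicate block (0.0544). The precursor rRNA spacers responded lower, with the 5' external spacer at -3.01, IS2 at -2.81 and the 3' external spacer at -2.62, and IGS was at -2.87. Mitochondrial MT-ND5 and MT-ND4 were at -2.25 and -2.27, and RNU1-1, which shares reads with its copies, at -1.49. MT-ATP6, an ATP synthase subunit, was at -2.88 (-2.27 without MNase exosome replicate 1 and -3.91 without MNase exosome replicate 2). MT-ND3 was at -4.35 (-6.80 without MNase exosome replicate 1 and -3.40 without MNase exosome replicate 2), on 1 count in MNase and 14 in untreated exosomes (ratio 13.7, exact 95% interval 2.09 to 579.9), and lost its call without untreated exosome replicate 1 or MNase exosome replicate 2 (adjusted p up to 0.443). RNVU1-7, at -1.11, lost its call without untreated cell replicate 2, MNase cell replicate 2, untreated exosome replicate 1 or 2 or MNase exosome replicate 1 or 2 (adjusted p up to 0.597). The nuclear long noncoding RNA NEAT1, at -2.09, lost its call without untreated exosome replicate 2 (adjusted p = 0.48), and KCNQ1OT1, at -2.19, lost its call without untreated cell replicate 1 or 2 or MNase cell replicate 2 (adjusted p up to 0.201). Left-out libraries moved the lower count to 22 (untreated exosome replicate 1), 23 (untreated exosome replicate 2) and 23 (MNase exosome replicate 2), and the higher count to 1 (untreated or MNase cell replicate 1, MNase exosome replicate 1 or 2, or untreated exosome replicate 2).

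For Triton plus MNase 66 features responded higher in exosomes and 105 lower. 7SL RNA was at -9.74 and its copies RN7SL2 and RN7SL3 at -5.31 and -7.39 (-8.45 without treated exosome replicate 1 and -6.62 without treated exosome replicate 2 for RN7SL3). IGS was at -4.09, IS2 at -3.83, RNU1-1 at -3.08, RNU1-3 at -3.39, NEAT1 at -2.38, MEG3 at -2.2, GAPDH at -2.27 and MT-ND5 at -1.94; with library size alone these turned to 0.37, 0.63, 1.38, 1.05, 2.08, 2.26, 2.16 and 2.52. VTRNA1-1, at -1.17, COL1A1, at -1.74, and MT-ND6, at -1.22, turned to 3.30, 2.71 and 3.24 with that scaling. VTRNA1-1 lost its call without untreated cell replicate 1 or treated cell replicate 2 (adjusted p up to 0.141), COL1A1 without treated cell replicate 2, untreated exosome replicate 1 or 2 or treated exosome replicate 1 or 2 (adjusted p up to 0.133) and MT-ND6 without untreated cell replicate 1 or 2, treated cell replicate 1, untreated exosome replicate 1 or 2 or treated exosome replicate 1 or 2 (adjusted p up to 0.305). The nucleolar protein gene NPM1 was at 3.74 (4.49 without untreated exosome replicate 1) and ANXA2 at 3.15. BCYRN1 had 0 counts in treated and 53 in untreated cells, at least 11.3-fold lower there, so its fitted 7.38 is no exact size. The higher count was 32, 39, 33 and 32 without untreated exosome replicate 1 or 2 and treated exosome replicate 1 or 2 in turn. Without untreated exosome replicate 1, untreated exosome replicate 2 or treated cell replicate 2 the lower count was 67, 58 and 67.

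Calls of further genes in that interaction ended when 1 library was left out. The splicing regulator gene PTBP1, at 3.58 (2.74 without untreated exosome replicate 1 and 6.05 without untreated exosome replicate 2) on 18 counts in treated and 1 in untreated exosomes (ratio 15.3, exact 95% interval 2.42 to 638), lost its call without untreated cell replicate 1, treated cell replicate 1, untreated exosome replicate 1 or 2 or treated exosome replicate 1 or 2 (adjusted p up to 0.318). LDHA, at 3.20 (4.03 without treated cell replicate 2 and 3.96 without untreated exosome replicate 2), lost its call without untreated exosome replicate 1 or treated exosome replicate 2 (adjusted p up to 0.31). PPIA, a cyclophilin gene, at 3.20 (3.80 without untreated exosome replicate 1), lost its call without treated exosome replicate 1 (adjusted p = 0.051). The chaperone gene HSP90AA1, at 3.12, lost its call without treated exosome replicate 1 or 2 or untreated exosome replicate 2 (adjusted p up to 0.135). TMEM158 had 0 counts in treated and 6 in untreated exosomes, at least 2.35-fold lower there, so its fitted -6.57 is no exact size, and it lost its call without untreated exosome replicate 1 or 2 or treated exosome replicate 2 (adjusted p up to 0.0818). The ribosomal protein genes RPS29, at 2.63, and RPL9, at 4.67 (3.78 without untreated exosome replicate 1 and 8.01 without untreated exosome replicate 2) on 8 and 2 counts (ratio 3.40, exact 95% interval 0.679 to 32.9), lost theirs without untreated cell replicate 2 or treated exosome replicate 1 (adjusted p up to 0.0762) and without untreated exosome replicate 1 or treated exosome replicate 2 (adjusted p up to 0.143). HIST1H2BG had 6 counts in treated and 0 in untreated exosomes, at least 1.70-fold higher there, so its fitted 7.14 is no exact size either, and it lost its call without untreated cell replicate 2, treated cell replicate 2, untreated exosome replicate 1 or 2 or treated exosome replicate 1 or 2 (adjusted p up to 0.154). CANX, at 2.27, lost its call without treated cell replicate 1, untreated cell replicate 2, untreated exosome replicate 1 or 2 or treated exosome replicate 2 (adjusted p up to 0.636), and CD63, at 2.60, lost its call without treated cell replicate 1, untreated cell replicate 2, untreated exosome replicate 1 or 2 or treated exosome replicate 1 or 2 (adjusted p up to 0.387). TOP2A, a topoisomerase gene of dividing cells, at 3.16 (2.55 without treated cell replicate 1, 5.09 without treated cell replicate 2, 4.89 without untreated exosome replicate 1 and 2.39 without untreated exosome replicate 2), lost its call without treated cell replicate 1, treated exosome replicate 1 or 2 or untreated exosome replicate 2 (adjusted p up to 0.196).

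7SL RNA fell 608-fold in exosomes under Triton plus MNase and was at 0.74 in cells. The tables argued against scaling as the whole cause, since the difference of effects nearest to 0 over the scalings was -5.27. Weaker digestion of the cell samples was argued against by the Y RNAs, whose median difference of effects was 0.95. Reads moving to gene copies were argued against by the 698 RN7SL copies, whose sum went from 21169 to 856 counts (log2 after scaling by the TMM factors, -4.93). Whether reads moved to repeat elements was not tested. One hypothesis is that 7SL RNA may be covered by SRP proteins in cells and not in exosomes, which would leave it open to the nuclease once membranes are dissolved. That stays untested, since no protein was measured and Triton without MNase was not analysed here. The difference in preparation between exosome and cell libraries was not tested as a cause either.

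Spacer counts of the rRNA precursor rose in cells under MNase. Genomic DNA as the source was argued against: the 5' external spacer gained 1350 CPM per kb and IGS 9.01, a ratio of 149.8. Scaling was argued against by the rise of that spacer relative to 28S rRNA in the same libraries, 3.03 in log2. One hypothesis is that RNA inside nuclei and mitochondria may be shielded from MNase in intact cells, with Triton opening mitochondria more than nuclei; separate nuclear or mitochondrial RNA was not analysed here, so it stays untested.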

How the results depend on the processing

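The alternatives with all assigned counts as library size were chosen after seeing the data; all others were planned before. Named genes kept their direction and their side of the threshold in 5286 of their alternative fits, gained a call in 111, lost one in 271 and turned in 222. Counts of called genes stayed within 1.5 times in 143 alternatives, were larger in 24 and smaller in 79. The minimum of 50 counts left 40 features in exosomes, 592 in cells and 603 over both, with TMM factors of their own, so calls there are not comparable with the main ones by number alone: the median feature went from 1.54 to -0.21 in untreated exosomes against cells, and to 0.71 and 1.15 in Triton plus MNase exosomes against untreated and MNase exosomes. Without a filter 50758, 19257 and 51412 were tested. Leaving out 1 library left 1 sample in its group, which was then assumed to vary like the other groups. Of the called named genes, the numbers that kept their call in each of these fits were 6 of 10 for exosome MNase against untreated, 14 of 16 for exosome Triton plus MNase against untreated, 8 of 8 for exosome Triton plus MNase against MNase, 33 of 41, 40 of 50 and 42 of 43 for the same contrasts in cells, 55 of 55 for untreated exosomes against cells, and 9 of 13 and 14 of 28 for the MNase and Triton plus MNase interactions. For the other changes the cause was not tested. For Triton plus MNase against untreated exosomes, the test found 52.2% of simulated 2-fold and 94% of 4-fold changes. These were in genes with a mean of at least 12 counts per library, so changes near 2-fold could be missed. Recovery of genes with fewer counts was not tested. The rates hold for the simulated counts only. Apart from the changed genes, the simulated libraries shared the same composition. The rates therefore do not show recovery in the real treated libraries, with gene-level counts of 170812 and 232588 and TMM factors of 5.04 and 4.97.

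Differences between replicates 1 and 2 correlated between groups at -0.0166 to 0.0428, which gave no sign that replicate numbers pair the samples. Counting noise in features of low count lowers such correlations, so pairing is not excluded. In cells the share of 5S rRNA was higher in replicate 2 than in 1 under all 3 treatments (2.89% against 2.41% untreated, 2.35% against 2.31% with MNase, 3.64% against 2.71% with Triton plus MNase). That of 7SL RNA was not. With the replicate block, higher and lower counts were 2 and 11, 2 and 39 and 0 and 26 for exosome MNase against untreated, Triton plus MNase against untreated and Triton plus MNase against MNase, 133 and 170, 758 and 730 and 549 and 472 for the same in cells, 6516 and 2131 for untreated exosomes against cells, and 1 and 35 and 64 and 101 for the interactions; the higher count of the MNase interaction, 1 against 2, was the only one to move by over 1.5 times. Over counts without ribosomal RNA, the 7SL RNA share was 15.7% in untreated, 12% in MNase and 16.2% in Triton plus MNase cells, and 63.9%, 51.3% and 0.263% in the exosomes of these treatments; this denominator moved 93 of the class shares by more than 1 SD.

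In exosome MNase against untreated, the higher count of 3 became 30 with library size alone, 1 with the minimum of 50 counts and 1 without rRNA and mitochondrial genes. Its 15 lower genes became 4 with library size alone, 0 with the minimum of 50 counts, 7 with all assigned counts and 9 in DESeq2. Between 5 and 17 genes were lower with 1 library left out (5 without exosome MNase replicate 1). RN7SL2 turned to 0.12, RNY1 0.091, BCYRN1 0.17 and SNORD3A 0.20 with library size alone. RN7SL2 turned to 0.054 and RNY1 0.037 with the minimum of 50 counts. SRP68 ran from -1.11 to 0.97, MT-RNR1 from -0.43 to 0.49, SNORD3A from -1.13 to 1.17, NEAT1 from -0.073 to 0.69 and SRPRB at -0.17 in the 1 such fit that tested it with 1 library left out.

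In exosome Triton plus MNase against untreated, the higher count of 2 became 13137 with library size alone, 19 with the minimum of 50 counts, 1 without rRNA and mitochondrial genes, 2959 with all assigned counts and 4 with all 12 libraries fitted. Between 2 and 5 genes were higher with 1 library left out (5 without exosome Triton plus MNase replicate 2). Its 41 lower genes became 13 with library size alone and 15 with the minimum of 50 counts. VTRNA1-1 turned to 2.87, VTRNA1-2 2.67, RN7SK 1.36, VTRNA1-3 3.03, BCYRN1 3.38, MT-CYB 2.28, MT-ND1 1.99, MT-RNR2 3.23, RPLP0 2.12, RPS19 2.22, MRPL16 2.96, HIST1H2BE 3.36, RNU1-1 1.98 and RNU4-2 1.87 with library size alone. SNORD3A turned to 2.52, SNORD3B-2 3.23, GAPDH 0.40, PDIA3 2.96, THY1 2.0, COL1A2 2.26, APOB 3.09, TF 3.42, TSG101 2.56 and MCM5 3.11 with library size alone. VTRNA1-1 turned to 1.80, VTRNA1-2 1.63, RNU1-1 0.92 and RNU4-2 0.77 with the minimum of 50 counts. VTRNA1-1 turned to 0.40, VTRNA1-2 0.21, VTRNA1-3 0.56, BCYRN1 0.92, MT-RNR2 0.78, SNORD3B-2 0.78, APOB 0.64 and TF 0.98 with all assigned counts. SRP72 ran from -0.013 to 5.21, MT-RNR1 from -0.33 to 0.52, HIST2H3C from -0.45 to 0.51, SNORD3A from -1.94 to 0.37, NEAT1 from -0.046 to 0.81, OIP5-AS1 from -0.18 to 1.37, PDIA3 from -1.18 to 0.077, HSPA5 from -0.21 to 1.87 and TF from -0.52 to 0.018 with 1 library left out.

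In exosome Triton plus MNase against MNase, the higher count of 0 became 13033 with library size alone, 23 with the minimum of 50 counts, 1838 with all assigned counts and 1 in DESeq2. Between 0 and 1 genes were higher with 1 library left out (1 without exosome Triton plus MNase replicate 1). Its 27 lower genes became 10 with library size alone and 12 with the minimum of 50 counts. VTRNA1-1 turned to 3.17, RN7SK 1.55, RNY4 0.28, SRP68 3.03, HERC6 2.2, MT-CYB 2.45, MT-ND1 2.35, RPL23A 1.28, RPL38 1.28, MRPL10 1.68, HIST2H3C 2.16, HIST1H2BE 2.56, RNU4-2 2.19 and RNU1-3 1.91 with library size alone. SNORD3A turned to 2.32, OIP5-AS1 2.66, GAS5 2.56, GAPDH 0.84, ALDOA 2.27, PDIA4 2.27, HSP90B1 2.33, THY1 1.86, FAP 2.05 and PTPRC 2.32 with library size alone. VTRNA1-1 turned to 0.15 and SRP68 0.044 without the low-count filter. VTRNA1-1 turned to 2.17 and RNU4-2 1.16 with the minimum of 50 counts. VTRNA1-1 turned to 0.97, SRP68 0.85, MT-CYB 0.26, MT-ND1 0.17 and OIP5-AS1 0.47 with all assigned counts. VTRNA1-1 turned to 0.031 in DESeq2. VTRNA1-1 turned to 0.027 with all 12 libraries fitted. VTRNA1-1 ran from -0.24 to 0.35, VTRNA1-2 from -0.22 to 0.53, VTRNA1-3 from -0.53 to 0.77, BCYRN1 from -0.28 to 0.50, SRP68 from -0.83 to 1.28, MT-RNR2 from -0.14 to 0.43 and MT-RNR1 from -0.34 to 0.53 with 1 library left out.

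In cell MNase against untreated, the higher count of 182 became 615 with library size alone, 121 without the low-count filter, 120 with the minimum of 50 counts, 621 with all assigned counts and 55 in DESeq2. Between 108 and 122 genes were higher with 1 library left out (112 without cell untreated replicate 2 and 108 without cell MNase replicate 2). Its 214 lower genes became 69 with library size alone, 115 with the minimum of 50 counts, 70 with all assigned counts, 51 in DESeq2 and 96 with all 12 libraries fitted. Between 128 and 153 genes were lower with 1 library left out (128 without cell MNase replicate 2). MMP1 turned to 0.081 with library size alone. MMP1 turned to 0.082 with all assigned counts.

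In cell Triton plus MNase against untreated, the higher count of 780 became 235 with library size alone, 217 with the minimum of 50 counts, 240 with all assigned counts and 255 in DESeq2. Its 761 lower genes became 1959 with library size alone, 223 with the minimum of 50 counts, 1945 with all assigned counts and 326 in DESeq2. 7SL turned to -0.27, RN7SL2 -0.51, VTRNA1-1 -0.50, VTRNA1-3 -0.81 and MT-RNR2 -0.19 with library size alone. 7SL turned to -0.26, RN7SL2 -0.50, VTRNA1-1 -0.49, VTRNA1-3 -0.80 and MT-RNR2 -0.18 with all assigned counts. VTRNA1-3 turned to -0.023 without the low-count filter.

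In cell Triton plus MNase against MNase, the higher count of 577 became 54 with library size alone, 337 without the low-count filter, 208 with the minimum of 50 counts, 57 with all assigned counts, 162 in DESeq2 and 248 with all 12 libraries fitted. Its 522 lower genes became 2791 with library size alone, 200 with the minimum of 50 counts, 2772 with all assigned counts and 226 in DESeq2. Between 338 and 412 genes were lower with 1 library left out (338 without cell Triton plus MNase replicate 2). 7SL turned to -0.15, RN7SL2 -0.46, RN7SL3 -0.81, VTRNA1-1 -0.30, VTRNA1-2 -0.61, VTRNA1-3 -0.63, LGALS3BP -0.73, MRPL4 -0.26, SNHG1 -0.029, MEG3 -0.29, COL1A1 -0.34 and COL6A1 -0.38 with library size alone. 7SL turned to -0.14, RN7SL2 -0.45, RN7SL3 -0.80, VTRNA1-1 -0.29, VTRNA1-2 -0.60, VTRNA1-3 -0.62, LGALS3BP -0.72, MRPL4 -0.25, SNHG1 -0.019, MEG3 -0.28, COL1A1 -0.33 and COL6A1 -0.37 with all assigned counts. MT-RNR2 turned to 0.024 with the minimum of 50 counts. MT-RNR2 ran from -0.072 to 0.029 with 1 library left out.

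In untreated exosomes against cells, the higher count of 7178 became 143 with the minimum of 50 counts, 2906 without rRNA and mitochondrial genes, 1188 in DESeq2 and 1838 with the 4 untreated libraries alone. Between 3168 and 5055 genes were higher with 1 library left out (4297 without cell untreated replicate 1, 3168 without cell untreated replicate 2 and 4779 without exosome untreated replicate 2). Its 2174 lower genes became 1008 with library size alone, 180 with the minimum of 50 counts, 1274 with all assigned counts, 789 in DESeq2 and 1237 with the 4 untreated libraries alone. RNY1 turned to 0.51 and BCYRN1 1.22 with library size alone. RNY1 turned to 2.54, RNY3 1.19 and RNY4 1.49 with the minimum of 50 counts. BCYRN1 turned to 0.24 with RLE factors. BCYRN1 turned to 0.27 without rRNA and mitochondrial genes. BCYRN1 turned to 0.71 with all assigned counts. BCYRN1 turned to 0.23 in DESeq2. BCYRN1 turned to 0.30 with the 4 untreated libraries alone. BCYRN1 ran from -0.22 to 0.070 with 1 library left out.

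In the MNase interaction, the higher count of 2 became 4 with RLE factors, 5 with library size alone, 1 without the low-count filter, 6 with the minimum of 50 counts, 1 with the replicate block, 1 without rRNA and mitochondrial genes and 4 in DESeq2. Between 1 and 3 genes were higher with 1 library left out (1 without cell untreated replicate 1, 1 without cell MNase replicate 1, 1 without exosome MNase replicate 1, 1 without exosome untreated replicate 2 and 1 without exosome MNase replicate 2). Its 36 lower genes became 23 with RLE factors, 23 with library size alone, 22 without rRNA and mitochondrial genes and 16 in DESeq2. Between 22 and 29 genes were lower with 1 library left out (22 without exosome untreated replicate 1, 23 without exosome untreated replicate 2 and 23 without exosome MNase replicate 2). 7SL turned to 0.030, RN7SL2 0.11, RN7SL3 0.20, VTRNA1-2 0.26 and RNY3 0.10 with RLE factors. 7SL turned to 0.070, RN7SL2 0.16, RN7SL3 0.25, VTRNA1-2 0.31 and RNY3 0.14 with library size alone. 7SL turned to 0.030, RN7SL2 0.11, RN7SL3 0.21, VTRNA1-2 0.25 and RNY3 0.10 in DESeq2. RN7SL3 turned to 0.010 and VTRNA1-2 0.071 without rRNA and mitochondrial genes. VTRNA1-2 turned to 0.043 with the minimum of 50 counts. VTRNA1-2 turned to 0.040 with all assigned counts. RN7SL2 ran from -0.40 to 0.24, RN7SL3 from -0.25 to 0.23, VTRNA1-2 from -0.43 to 0.36, VTRNA1-3 from -1.0 to 0.008 and TF from -2.60 to 0.15 with 1 library left out.

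In the Triton plus MNase interaction, the higher count of 66 became 8808 with library size alone, 35 without the low-count filter, 2787 with all assigned counts and 11 in DESeq2. Between 32 and 59 genes were higher with 1 library left out (32 without exosome untreated replicate 1, 33 without exosome Triton plus MNase replicate 1, 39 without exosome untreated replicate 2 and 32 without exosome Triton plus MNase replicate 2). Its 105 lower genes became 5 with library size alone, 55 without the low-count filter, 63 with the minimum of 50 counts, 159 without rRNA and mitochondrial genes, 32 with all assigned counts and 48 in DESeq2. Between 58 and 109 genes were lower with 1 library left out (67 without cell Triton plus MNase replicate 2, 67 without exosome untreated replicate 1 and 58 without exosome untreated replicate 2). VTRNA1-1 turned to 3.30, RNY1 4.0, VTRNA1-2 4.09, RN7SK 3.54, VTRNA1-3 3.77, IGS 0.37, IS2 0.63, LGALS3BP 1.80, MT-ND5 2.52, MT-ND6 3.24, MT-RNR2 3.37, RNU1-1 1.38, RNU1-3 1.05 and SNORD3C 2.0 with library size alone. SNORA73B turned to 1.08, NEAT1 2.08, MEG3 2.26, GAPDH 2.16, COL1A1 2.71, COL1A2 2.79, KRT80 1.36, TF 1.77 and PTPRC 3.38 with library size alone. VTRNA1-1 turned to 0.89, RNY1 1.60, VTRNA1-2 1.68, RN7SK 1.14, VTRNA1-3 1.36, MT-ND5 0.11, MT-ND6 0.83, MT-RNR2 0.96, COL1A1 0.30, COL1A2 0.39 and PTPRC 0.98 with all assigned counts. PTPRC ran from -0.57 to 0.016 with 1 library left out.

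Scaling the repeat families by their own TMM factors moved their counts from 117 lower to 27 in exosome MNase against untreated, 252 lower to 62 in exosome Triton plus MNase against untreated, 2 lower to 1 in exosome Triton plus MNase against MNase and 183 higher to 17 and 14 lower to 45 in cell MNase against untreated. Further moves were from 204 higher to 42 and 14 lower to 53 in cell Triton plus MNase against untreated, 80 higher to 4 and 2 lower to 19 in cell Triton plus MNase against MNase, 705 higher to 76 in untreated exosomes against cells and 2 higher to 10 and 264 lower to 26 in the MNase interaction. The last were from 5 higher to 19 and 311 lower to 42 in the Triton plus MNase interaction. Lists past camera's test went from 4 to 1 with an estimated correlation and 0 in fry in exosome MNase against untreated, from 5 to 3 with an estimated correlation in exosome Triton plus MNase against untreated, from 4 to 2 with an estimated correlation and 2 in fry in exosome Triton plus MNase against MNase, from 10 to 5 with an estimated correlation in cell MNase against untreated and from 10 to 0 with an estimated correlation in cell Triton plus MNase against untreated. They also went from 13 to 6 with an estimated correlation in cell Triton plus MNase against MNase, from 4 to 1 with an estimated correlation and 1 in fry in the MNase interaction and from 10 to 6 with an estimated correlation in the Triton plus MNase interaction.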

Other observations

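The antisense ratio and the rho between exosomes and cells below were set as tests before the result was seen. By the rule set then, a rho as low as the one found counted against RNA of the cells. The comparison with the rho between replicates, which left that test undecided, was not part of that rule. The test over genes with no cell count and the other values were picked out afterwards. In cells, RNA polymerase III small RNAs fell in 7 of 8 cases under MNase alone, also adjusted over the list alone (adjusted p = 0.0432 with an estimated correlation), and under Triton plus MNase 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0577 with an estimated correlation). Glycolysis genes fell in 9 of 16 cases under Triton plus MNase with 1 higher, also adjusted over the list alone (adjusted p = 0.136 with an estimated correlation). ER chaperone genes fell in 7 of 14, 8 adjusted over the list alone (adjusted p = 0.122 with an estimated correlation). Exosome-associated protein genes fell in 5 of 11 and rose in 2, also adjusted over the list alone (adjusted p = 0.136 with an estimated correlation). SRP protein genes fell in 3 of 6, also adjusted over the list alone, without a call of the list (adjusted p = 0.349 with an estimated correlation). Against MNase alone, Triton plus MNase left 14 of 17 spliceosomal snRNAs higher and 1 lower, 14 and 2 adjusted over the list alone (adjusted p = 0.0495 with an estimated correlation), but with library size alone 1 was higher and 4 were lower.

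Mitochondrial tRNAs held 0.0488% ± 0.0132 of all assigned counts (SD, n = 2) in untreated cells, 0.0672% ± 0.00689 after MNase and 0.00441% ± 0.000471 after Triton plus MNase, while the transcribed spacers of precursor rRNA held 0.114% ± 0.00231, 0.940% ± 0.0416 and 0.991% ± 0.0276. In exosomes the shares of Alu elements were 9.32% ± 0.499, 16.3% ± 0.328 and 36.6% ± 0.277 and those of IGS 0.714% ± 0.0364, 1.44% ± 0.00293 and 3.37% ± 0.00667 in the same order of treatments.

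Untreated exosome libraries held low counts over most genes and repeats, and whether these came from RNA of the co-cultured cells stays open for genes that cells express: exosome and cell counts per kb over protein-coding genes had a Spearman rho of 0.0898 across genes, which are not independent replicates, but the 2 untreated exosome replicates reached only 0.169, so the test could not tell. The 100 genes densest in untreated cells had 3.10 exosome counts per kb, against 0.773 over all genes with a cell count and 0.694 over genes with none. Over genes with no cell count the density was 0.897 times that over genes with one, which argued against RNA in the proportions of the cells as the source of those counts. Genomic DNA in the exosome libraries may account for them: repeat copies antisense to protein-coding genes were as dense as copies of the same families outside genes, with a ratio of 1.01. In cells the same ratio ranged from 0.871 to 1.02, on far fewer counts, so the ratio alone does not set DNA apart from unspliced or read-through RNA, which stays open. After Triton plus MNase the exosome libraries held 0.805 raw counts per kb over genes with no cell count, against 0.694 in untreated ones. Since levels are relative within a library, these values do not show how much of this material the nuclease removed.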
